A study of Mus musculus with 6 samples.

How the data were processed

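The libraries measured circRNA-SIINFEKL in synthetic RNA that was not transfected (3 libraries) and in mouse bone marrow dendritic cells 24 h after transfection (3 libraries). Per the labels' protocols, ribosomal RNA was depleted, linear RNA was digested with RNase R, and the remaining RNA was fragmented and converted to stranded libraries for paired-end sequencing. Bowtie2 and SAMtools are named in the submitters' processing notes, without versions or settings. The variant caller, its filters and the minimum depth are not given in the sources used here. Groups were taken from the sample titles. The treatment field gives no treatment for the dendritic cell samples, whereas their titles name treatment with circRNA, and the titles were followed.

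The authors deposited 1 table with 2 blocks of columns. Per the file headers, each block holds the position, the reference base, the alternative base, an allele fraction for each of 3 libraries, and their mean. The position and reference base were identical in both blocks at all 111 positions, and these are the values used. The 6 library columns, the 2 mean columns and the 2 columns of alternative bases were not used. The library names in the headers match no title or description, and no header names a group. Column order does not identify a group, and assigning the blocks by their values would have fixed the outcome of the comparison in advance. Read depth is unknown, so no counting error could be attached to any fraction.

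The tests fixed before the data were examined were therefore not run. They were an exact permutation test of the mean allele fraction per library, a limma test per position, counts of positions above a threshold, correlations between libraries, and comparisons by substitution class and by region. The comparisons between groups need each column's group. Counts of positions and correlations within and between the unnamed blocks do not, and they were left out because columns that match no sample of the series were not used for any value. With 3 libraries in each group, the smallest two-sided p that the exact permutation test allows is 0.10. The rule for naming positions relied on allele fractions and named none. No gene is named. The analyses of the reference sequence were chosen after the table was seen, except the search for the SIINFEKL codons.

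The reference sequence was read from the table and translated in the 3 forward frames with the standard genetic code to find the SIINFEKL codons. Each ATG was extended to the first stop codon or to the last base. Base composition was counted over the whole sequence, by segment and in windows of 15 nt. Exact matches to GENCODE M21 mouse transcripts (GRCm38) were found by extending every shared 14 nt word, on both strands and with the last reference base joined to the first. The search was repeated for 100 shuffled references that kept the dinucleotide counts. As alternatives, it was repeated on the linear reference and on 58797 protein-coding transcripts alone, and GC content was counted in windows of 9 nt and 21 nt. The frame search and the match search were tested on made sequences with known answers. The build the authors aligned to is not given in the sources used here, and no genome coordinates are reported. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used. The scipy library was also loaded, for an interval on window GC content that is not reported here, and its version was not recorded.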

Results

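Sequencing of circular RNA was used to follow the base sequence of circRNA-SIINFEKL, a synthetic circular RNA that encodes the ovalbumin peptide SIINFEKL, a model antigen presented by mouse MHC class I. Circular RNA has no free ends and resists exonucleases such as RNase R, the enzyme used here to digest linear RNA before library construction. The design comprised 6 libraries in 2 groups. In the first group, 3 libraries were made from synthetic circRNA that had not been transfected, which served as the control. In the second group, 3 libraries were made from RNA of mouse bone marrow dendritic cells, antigen-presenting cells grown from marrow, 24 h after transfection with the circRNA. The comparison implied by this design asked whether the circRNA recovered from live cells carried sequence changes that the untransfected circRNA lacked.

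That comparison was not made, because the measurements could not be tied to the groups. The deposited table listed 111 positions of the circRNA in 2 blocks, each with 3 library columns of allele fractions. The names of the 6 library columns occurred in no sample label, and both blocks carried the same heading. Neither block could therefore be assigned to the synthetic circRNA or to the dendritic cells without relying on column order or on the measured values themselves. The allele fractions are not analysed here, and no statement is made on whether the sequence differed between the groups. The depth behind these fractions is unknown. The results below describe the reference sequence that both blocks shared, and they are properties of a sequence without replicates or error.

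The reference sequence ended with the SIINFEKL codons. Translation of the listed strand found the peptide in 1 place, at positions 88 to 111, where the 24 nt AGTATAATCAACTTTGAAAAACTG encode it. Positions are counted from 1 at the first listed base. The listed strand held 1 ATG, at positions 82 to 84, in frame with the antigen. It lay within GCCACCATGG at positions 76 to 85, a sequence known as a strong Kozak context for translation initiation. Read from this ATG to the last listed base, the frame encoded the 10 residues MESIINFEKL and contained no stop codon. If the listed positions are the whole circle in its ligated order, the frame continues past position 111. Under that reading it ends at a TAG stop codon that begins at position 16. The remaining 81 nt lay upstream of the ATG in the listed order. The labels do not annotate that segment, and no function was assigned to it.

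The reference was rich in A and T. Of its 111 bases, 46 were T (41.4%), 32 were A (28.8%), 21 were G (18.9%) and 12 were C (10.8%), so that GC content was 29.7%. GC content was 29.6% upstream of the ATG and 30.0% from the ATG to the end, and it was 25.0% within the SIINFEKL codons. In the listed linear order, the base makeup of the segments nevertheless differed in which of A and T dominated. T made up 46.9% and A 23.5% of the 81 nt upstream of the ATG. In contrast, A made up 43.3% and T 26.7% of the 30 nt from the ATG to the last listed base. This contrast depends on where the listed sequence starts. Read as a circle, the antigen frame would continue into positions counted here as upstream. Base makeup was not counted for that reading. In windows of 15 nt, GC content ranged from 0.0% at positions 19 to 33 to 66.7% at positions 75 to 89, one of the windows that hold the ATG.

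**Figure D1:**
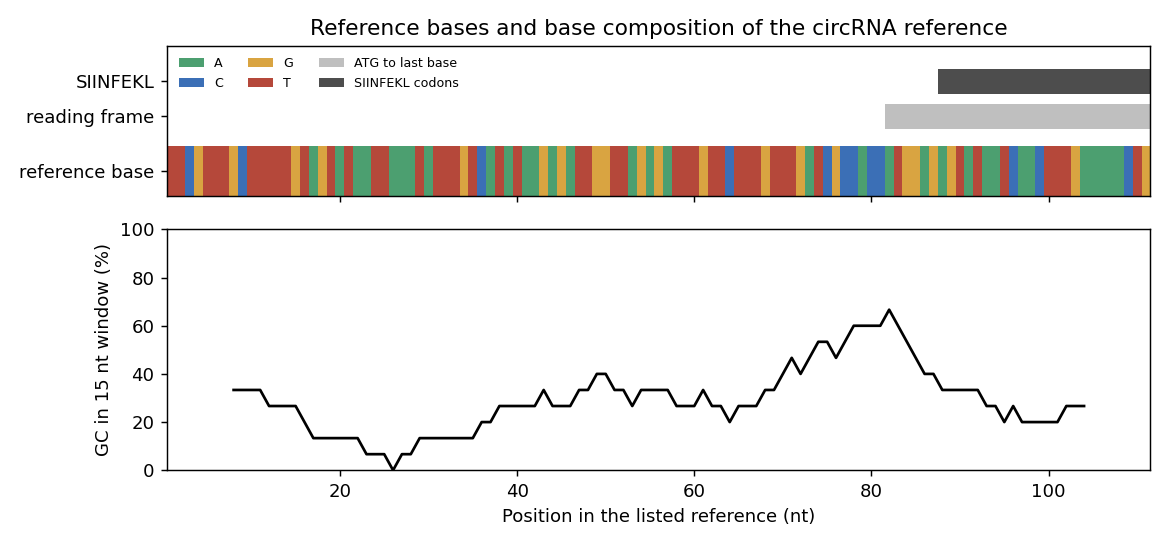
Reference bases of circRNA-SIINFEKL by position (upper panel, 1 coloured bar per base, with the reading frame and the SIINFEKL codons as grey bars) and GC content in percent in sliding windows of 15 nt, plotted at the window centre (lower panel). GC content reaches 66.7% at positions 75 to 89 and 0.0% at positions 19 to 33.

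The reference was also compared with mouse transcripts. The dendritic cell libraries were made from RNA of mouse cells after depletion of ribosomal RNA and digestion of linear RNA, and how much mouse RNA remained in them was not measured here. Across 141767 GENCODE M21 transcripts, the longest exact match to the listed strand was 17 nt of the 111 nt. The longest match to the opposite strand was 18 nt. Matches of this length were also found for shuffled sequences. Among 100 shuffles of the reference that kept its dinucleotide counts, the longest match had a median of 17 nt on either strand, and it was at least as long as the observed one in 83 shuffles on the listed strand and in 39 on the opposite strand. Both observed lengths lay within the range of the shuffles, which was 15 to 20 nt on the listed strand and 15 to 21 nt on the opposite strand, and the genes that held them are not singled out. In protein-coding transcripts alone, the longest match on the opposite strand was 16 nt. Alignments with mismatches were not examined. Neither was mouse sequence outside the annotated transcripts, including the junctions of mouse circular RNA.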

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

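No paired analysis was possible because the library columns carry no replicate number and could not be matched to samples. Checks that need the library columns, such as leaving out each replicate, were not run, since those columns were not used. Alternatives for the reference sequence were chosen after seeing the data. In protein-coding transcripts alone, the longest match was 17 nt on the listed strand, as in all transcripts. It was 16 nt on the opposite strand, against 18 nt in all transcripts. A smaller set cannot give a longer match, but it need not give a shorter one. The 18 nt match lay only in transcripts not typed as protein-coding, which does not give the type of the gene. Shuffled references were not searched in protein-coding transcripts alone. A search of the linear reference tests nothing here, because no longest match crossed from the last base to the first. The highest GC content was 66.7% in windows of 9 nt and 52.4% in windows of 21 nt, and the lowest was 0.0% and 9.5%. Read depth is unknown and limits any later use of the fractions.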

Other observations

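All analyses in this part were chosen after the table was seen. Read as a circle, with position 111 joined to position 1, the frame of the SIINFEKL codons does not end at the last listed base. It continues for 5 further residues to a TAG stop codon that begins at position 16, giving the 15 residues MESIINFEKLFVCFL. This holds only if the 111 listed positions are the whole circle in its ligated order, which the labels do not state. Under that reading, the stop codon of the antigen frame lies on the other side of the junction from its ATG.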
